A study of Mus musculus with 12 samples.

How the data were processed

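The series holds 12 samples, 10 of bulk tissue and 2 of single cells, all from mouse cortex. Tissue came from homozygotes and heterozygotes for Cx3cr1CreErt2 that had received tamoxifen on postnatal days 1 to 3 and had the right whiskers cauterized on day 4, so that the left cortex is deprived and the right cortex spared, per the labels. Tissue cDNA was made with a NuGEN Ovation kit and sequenced as single reads of 75 cycles, per the labels' protocols. The cell samples are inDrops libraries of about 3000 cells each, called mixed in the labels, and the names of the deposited count tables give genotype, hemisphere and number for 16 libraries.

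The tissue table holds RPKM (reads scaled to gene length and to the reads counted in genes), deposited by the authors, and the submitters' processing notes name bcl2fastq, TopHat2 2.1.0, HTSeq 0.6.0, DESeq2 and the build mm9. The single-cell tables hold whole-number counts per barcode and gene as deposited, and the submitters' processing notes name Trimmomatic 0.32, Bowtie 1.1.1 and the build GRCm38. The deposited cluster table gives the number, 0 to 27, that the authors assigned to each of 33783 cells, and its column name names Seurat. No doublet detection was run on the annotated cells, and the deposited files and labels do not say whether the authors removed doublets. The authors' normalized cell matrix was not used because tests need raw counts. Coordinates are those of GRCm38; none are given for mm9, the build of the tissue table.

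Tissue was tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), for genes with a mean of at least 1 RPKM over the 10 libraries. The test used lmFit and eBayes with a trend, with genotype as a covariate, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Contrasts within a genotype and the interaction came from 4 group means. Homozygotes and heterozygotes were compared on the mean of both hemispheres of each animal. Whole reads could be recovered from 100% of the RPKM values (tolerance 0.1 read), and edgeR 4.0.16 was run on them as an alternative.

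Cell counts were summed per genotype, hemisphere, number and cluster over both libraries of a sum, giving 8 sums, and tested with edgeR's quasi-likelihood test with TMM factors and filterByExpr, adjusted within each cluster. The 21 clusters with at least 20 cells in each sum were tested; clusters 15, 17, 19, 23, 25, 26 and 27 were left out for too few cells. Knockouts and heterozygotes were compared on sums over both hemispheres. Clusters were named from marker lists fixed beforehand; "-like" marks such a name, and clusters without a clear match stay unnamed. CPM are counts divided by the summed counts of the cells, times the usual scale. Shares of cells were compared by a two-sided exact permutation test over 70 arrangements, and fractalkine genes by two-sided exact sign flips of pairs. Intervals are exact 95% binomial or Poisson intervals and cover counting error; a count of 0 allows up to 3 counts.

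Gene lists, 34 of which were fixed, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 3 members were measured. The tests, the alternatives, the gene lists and the rule for named genes were set before the data were examined, except for those named as added later. The rule names every member of the fractalkine list, with Cx3cr1 first. It then names up to 10 genes in each direction with the largest fold change among those past the threshold with the same sign in every pair, or without overlap between genotypes. Where fewer than 5 pass in a direction, it names these and the 5 with the smallest p as values. From each list past the threshold it names the 4 members with the smallest p. For clusters other than microglia and the one with the most calls it names the 2 genes with the smallest adjusted p in each direction. Predicted genes, pseudogenes and ribosomal protein genes are counted but not named. Some genes that the rule picks are not reported here.

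The numbers were taken to pair the libraries. In tissue the hemispheres of an animal share its number, and their deviations from the group means correlated at 0.164 (animal 1), 0.371 (3), 0.493 (54), and 0.412 for animals 4 and 55, which are 1 value by construction since their group has 2 animals. Animals 1 and 55 correlated more with another number (0.184 and 0.439). In cells the name without the hemisphere gave 8 animals, with median correlations over 15 clusters of 0.168 to 0.257 and a lowest value of -0.185. The library with the same name was the best match in 4 to 14 of the 15 clusters, with 5 and 4 for both heterozygotes of sample 1. In each sum the first library had Xist at 0.385 to 18.8 CPM and Ddx3y at 71.8 to 84.7 CPM, and the second had Xist at 1232 to 1769 CPM and Ddx3y at 0.184 to 0.920 CPM, so that each sum holds a male and a female and each genotype 4 animals. Fits with each library as a replicate (at least 10 cells per library) were therefore added after the data were seen. So were the exact sign flips of pairs, edgeR on tissue and the fit without animals 3, 4 and 54. The covariate, a mean z-score of 52 leading genes of clusters 8, 13 and 17, was also added then.

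Other alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 RPKM, median scaling, quantile normalization, eBayes without trend, the replicate number as a block (the animal in tissue and for single libraries, a pair of animals for sums), spared hemispheres only, DESeq2 1.42.0, library size only, other filters on counts, cells with at least 1000 UMIs, 1 library of each sum only, adjustment over all cell types and leaving out each library or sum. The procedures were tested on simulated data with 200 changed genes. For tissue, deprived against spared, they recovered 43% of genes changed 1.5-fold and 92% of those changed 2-fold. In microglia-like cells, for both genotypes together, they recovered 38% of genes changed 2-fold and 97% of those changed 4-fold, and in heterozygotes 12% and 88%. Computation used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with the R package data.table in version 1.17.8.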

Results

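The series profiled mouse barrel cortex, the field of primary somatosensory cortex that receives input from the whiskers, at postnatal day 5, after the whiskers on 1 side of the face had been cauterized at day 4. Cx3cr1 encodes the receptor for fractalkine (Cx3cl1), a membrane-anchored chemokine of neurons that proteases such as Adam10 and Adam17 can release from the cell surface. The comparisons ask what whisker lesion changes in the deprived hemisphere, and whether animals without Cx3cr1 differ. Bulk RNA was measured in 10 tissue libraries from 5 animals, each with a left (deprived) and a right (spared) cortex. Homozygotes for the Cx3cr1CreErt2 allele, which interrupts Cx3cr1, were animals 1, 3 and 54, and heterozygotes were animals 4 and 55. The tissue libraries held 20075948 to 62784840 reads in genes. Single cells were measured by inDrops, a droplet method that counts molecules with unique molecular identifiers (UMIs), in 16 libraries from heterozygotes and knockouts, deprived and spared. The authors' annotation placed 33783 of the 95071 deposited barcodes in 28 clusters, with a median of 2479 counts and 1375 genes per cell. The annotated cells of a library summed to 2966672 to 10668993 counts.

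Cx3cr1 followed the genotype labels in every library. It lies on chromosome 9 (GRCm38, 119901616 to 120069879, minus strand). In tissue its level was 0, 0, 0 and 0 RPKM in 4 of the 6 homozygous libraries and 0.0108 and 0.0469 RPKM in the deprived libraries of animals 1 and 3, against 0.370 and 0.330 RPKM (animal 4) and 0.190 and 0.134 RPKM (animal 55) in heterozygotes, deprived before spared. These levels rest on 0 to 8 Cx3cr1 reads in homozygotes and 19 to 38 in heterozygotes. In microglia-like cells Cx3cr1 was 1175 ± 287 CPM (the count scaled to the summed counts of these cells) in heterozygotes and 63.3 ± 47.6 CPM in knockouts (SD, n = 8 libraries each), and the ranges, 837 to 1592 and 0 to 148 CPM, did not overlap.

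Deprived tissue differed from spared tissue in more genes that were lower than higher. Of 11498 genes, 72 passed limma's test at an adjusted p under 0.05, 13 higher and 59 lower in deprived than in spared cortex, and all 72 had the same sign in 5 of 5 animals. Among the higher genes, Cux2, a transcription factor of layers 2 to 4, was at 19.4 ± 2.23 RPKM in deprived and 10.1 ± 2.37 RPKM in spared tissue (SD, n = 5), a log2 fold change of 0.93 ± 0.16 (SE, adjusted p 0.0270 by limma). The small heat shock protein gene Hspb3 was at 11.1 ± 0.629 against 4.57 ± 1.73 RPKM (log2 1.27), and the calcium channel gene Trpv6 at 3.42 against 1.44 RPKM (1.05). The receptor tyrosine phosphatase Ptprk was at 18.3 against 10.6 RPKM (0.77) and the ephrin receptor Ephb6 at 4.15 against 2.21 RPKM (0.78). Ramp3 (0.72), the formin Fhod3 (0.60), Fam124a (0.54), the hedgehog co-receptor Boc (0.54) and the T-cell receptor joining segment Trbj2-3 (2.09, from 0.173 to 2.39 RPKM) complete the 10 largest rises past the threshold. Trbj2-3 was at 0 RPKM in the spared libraries of animals 1, 3 and 4. It did not pass edgeR's filter on counts, so that its fold rests on a spared level near 0.

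Among genes past the threshold, the largest fall was that of Nrp2, a semaphorin co-receptor that steers growing axons (chromosome 1, 62703285 to 62818695, plus strand, GRCm38). It was at 0.858 ± 0.122 RPKM in deprived and 7.81 ± 2.94 RPKM in spared tissue (SD, n = 5), a log2 fold change of -2.55 ± 0.19 (SE, adjusted p 0.000604 by limma). The transcription factors Zic1 (1.14 against 8.48 RPKM, log2 -2.33), Ebf3 (0.577 against 4.26 RPKM, -1.94), Otx2 (0.0787 against 2.03 RPKM, -1.93) and St18 (5.97 RPKM in spared tissue, adjusted p 0.0135 by limma) fell. The neuropeptide gene Nts was at 3.31 ± 1.61 against 15.5 ± 6.08 RPKM (-2.08), the neuropeptide Y receptor Npy2r at 0.540 against 2.93 RPKM (-1.66), and Nrn1, a secreted factor whose transcription follows neuronal activity, at 5.04 ± 0.626 RPKM in deprived tissue (-1.54). Ankrd43 (-1.72) and the lipid transfer gene Tnfaip8l3 (-1.68) complete the 10 largest falls past the threshold. In the single cells Nrp2 is among the leading genes of cluster 8 and Otx2 among those of ependymal or choroid plexus-like cluster 15. Zic1 and Ebf3 lead Cajal-Retzius-like cluster 21, and Nts leads excitatory clusters 3 and 19. Whether these falls, or the rises above, lie within cells of the barrel cortex is left open below. Folds are on the scale of log2(RPKM + 0.5), which understates the change of genes near 0.

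**Figure D1:**
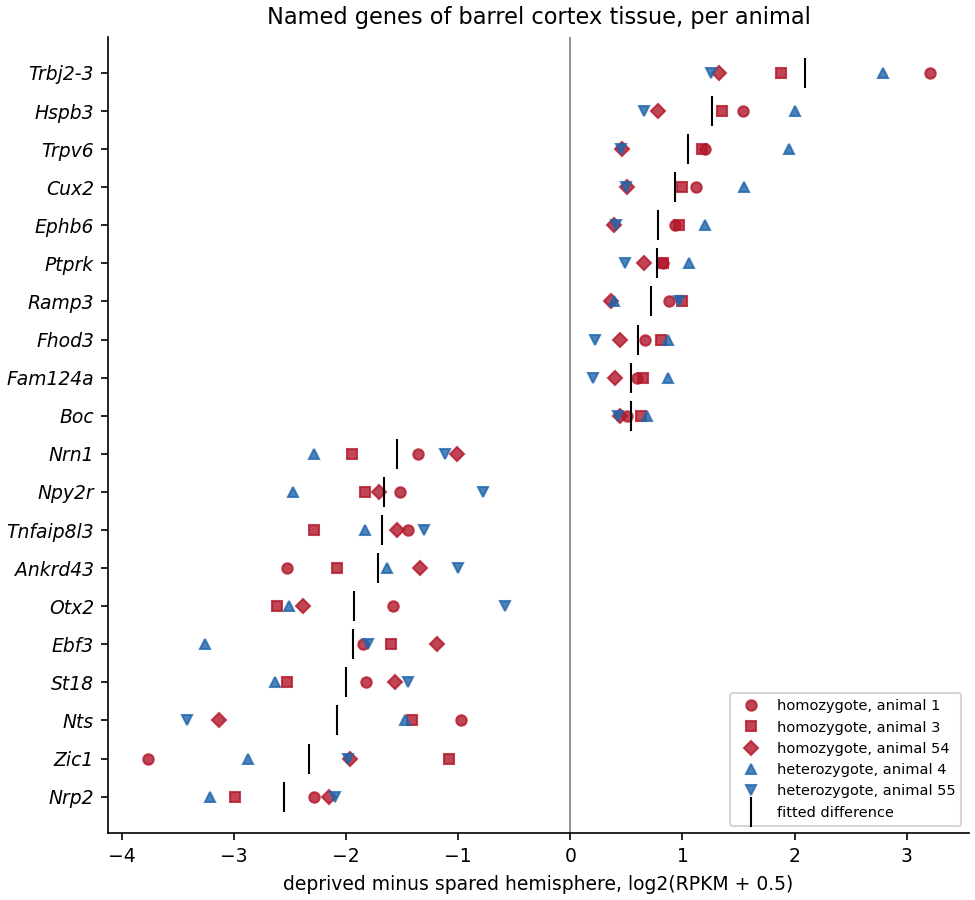
Difference between the deprived and the spared hemisphere in log2(RPKM + 0.5) for the 20 named genes with the largest changes past the threshold, with 1 symbol per animal (homozygotes in red, heterozygotes in blue) and a black bar for the fitted difference. Each gene lies on the same side of 0 in 5 of 5 animals, with fitted values from -2.55 (Nrp2) to 2.09 (Trbj2-3, from a spared level near 0).

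The count of 72 rested on few animals. With the animal as a block it was 364, and with edgeR on the whole reads recovered from the RPKM values it was 280. Without a filter on low RPKM it was 14. Leaving out 1 library gave between 14 (without spared 3) and 524 (without spared 55); deprived 55, 4, 1, 3 and 54 and spared 4 gave 15, 24, 24, 28, 35 and 31 when left out.

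Genes of the upper and middle layers passed upward as a group in deprived tissue at a preset correlation. Of the 32 gene lists with at least 3 measured members, 11 passed camera with the preset correlation, 3 up and 8 down, and none passed with an estimated correlation. Of 12 measured genes of layers 2 to 4, 11 had a positive log2 fold change with a median of 0.67 (adjusted p 1.98e-08 by limma's camera). This list's adjusted p = 0.249 with an estimated correlation. One of its members passed over all genes (Cux2) and 9 passed when adjusted over the list alone. Rorb, the nuclear receptor of layer 4 (chromosome 19, 18930605 to 19111196, minus strand, GRCm38), was at 69.0 ± 7.34 against 36.9 ± 10.3 RPKM (log2 0.94), the potassium channel Kcnh5 at 10.5 against 5.06 RPKM (0.96) and Rasgrf2 at 16.2 against 13.2 RPKM (0.29). The list of excitatory neuron genes also passed upward (adjusted p 0.0330; adjusted p = 0.581 with an estimated correlation; 3 of 9 adjusted over the list alone), with log2 fold changes of 0.74 for Emx1, 0.31 for Tbr1 and 0.39 for Neurod2. Cholesterol synthesis passed upward with small folds, a median of 0.14 over 13 genes (adjusted p 0.0128; adjusted p = 0.581 with an estimated correlation; 0 adjusted over the list alone), led by Fdft1 (0.23), Idi1 (0.21) and Insig1 (0.18).

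Activity-regulated genes passed downward as groups at the preset correlation. Immediate early genes, which neurons transcribe within minutes of stimulation, passed downward (16 measured, median log2 -0.28, adjusted p 0.000257 by limma's camera; adjusted p = 0.249 with an estimated correlation), with 0 over all genes and 4 adjusted over the list alone. Fos (chromosome 12, 85473890 to 85477273, plus strand, GRCm38) was at 0.705 ± 0.201 against 1.68 ± 0.461 RPKM (log2 -0.84, lower in 5 of 5 animals, adjusted p 0.0654 over all genes by limma), Nr4a2 at 27.9 against 44.0 RPKM (-0.65), Jun at 8.53 against 10.4 RPKM (-0.27) and Npas4 at 0.837 against 1.59 RPKM (-0.59). Late response genes passed downward too (13 measured, median -0.38, adjusted p 0.00691; adjusted p = 0.249 with an estimated correlation; 1 member over all genes, Nrn1; adjusted over the list alone, 4 lower and 1 higher). Besides Nrn1 they held the growth factor gene Bdnf at 0.502 against 1.55 RPKM (log2 -0.97) and Vgf at 0.735 RPKM in deprived tissue and lower than spared, while Plk2 was at 102 against 78.2 RPKM (0.39).

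Lists of other cell types and of tissue next to the cortex passed downward at the preset correlation. Inhibitory neuron genes passed downward (13 measured, median log2 -0.38, adjusted p 0.00860 by limma's camera; adjusted p = 0.581 with an estimated correlation; adjusted over the list alone, 5 lower and 1 higher), with Gad2 at 37.8 ± 4.89 against 105 ± 51.4 RPKM (-1.28), Gad1 at 5.04 against 11.5 RPKM (-1.01), Adarb2 (-0.62) and Dlx6os1 (-0.33). Choroid plexus and ependymal genes passed downward (3 measured, adjusted p 0.00685; adjusted p = 0.522 with an estimated correlation; 3 lower adjusted over the list alone). Ttr, the transthyretin of choroid plexus, was at 547, 265 and 228 RPKM in the spared libraries of animals 54, 3 and 4 and at 2.69 and 1.3 RPKM in those of animals 1 and 55, against at most 1.12 RPKM in the 5 deprived libraries. Clic6 was at 0.228 against 1.91 RPKM (log2 -1.50) and Foxj1 at 1.04 against 1.47 RPKM (-0.35). The list of thalamus and striatum genes passed downward (7 measured, median -0.62, adjusted p 0.0384; adjusted p = 0.581 with an estimated correlation; 0 adjusted over the list alone), with Tcf7l2 at -0.91, Rgs9 at -0.38, Drd2 at -0.90 and Adora2a at -0.82. Cajal-Retzius genes passed downward (3 measured, adjusted p 0.0314; adjusted p = 0.565 with an estimated correlation; 2 lower adjusted over the list alone), with Calb2 at 1.79 against 6.94 RPKM (-1.55), Cacna2d2 (-0.60) and Reln (-0.09).

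Astrocyte and interferon genes also passed downward. Of 12 astrocyte genes 11 were negative, with a median log2 of -0.28 (adjusted p 0.0165 by limma's camera; adjusted p = 0.653 with an estimated correlation; 0 adjusted over the list alone), as in Slc1a3 (-0.37), Slc4a4 (-0.39), Gfap (-0.52) and Gja1 (-0.44). All 14 interferon response genes were negative, with a median of -0.34 (adjusted p 0.00563; adjusted p = 0.581 with an estimated correlation; 0 adjusted over the list alone), as in Oasl2 (-0.64), Ifit1 (-0.66) and Cxcl10 (-0.60). The other 21 lists, among them homeostatic microglia, activated microglia, complement, presynaptic and postsynaptic genes and the fractalkine list, did not pass. With the animal as a block 12 lists passed: astrocyte reactivity (adjusted p 0.0311), immature neurons (0.0338) and leptomeningeal fibroblasts (0.0381) came in, excitatory neurons and thalamus or striatum dropped out, and none passed with an estimated correlation. Without deprived 1, 7 lists passed.

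Genes that lead several cell clusters passed as groups between the tissue hemispheres at the preset correlation, and none did with an estimated correlation. Genes leading the Zic1 and Ndnf cluster of the single cells (cluster 21, Cajal-Retzius-like) had a median tissue log2 fold change of -0.82, from -1.41 in animal 1 to -0.07 in animal 55. Those of cluster 15 (ependymal or choroid plexus-like) had -0.736, those of the Prox1 cluster (cluster 8) -0.54 and those of the Crym cluster (cluster 13) -0.48. Inhibitory neuron-like clusters 11 and 7 had -0.425 and -0.384, and cluster 23 (ependymal or choroid plexus-like) had -0.36. Genes of cluster 17 had a median of -0.04 and did not pass (adjusted p 0.492 at the preset correlation, by limma's camera). Those of cluster 14, which has no name, had -0.43, from -1.53 in animal 1 to 0.55 in animal 55, while genes leading the Rorb and Cux2 cluster (cluster 0) had 0.40 and those of the Ptprk cluster (cluster 1) 0.36. No cluster's genes passed with an estimated correlation (the lowest adjusted p was 0.136, by limma's camera).

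**Figure D2:**
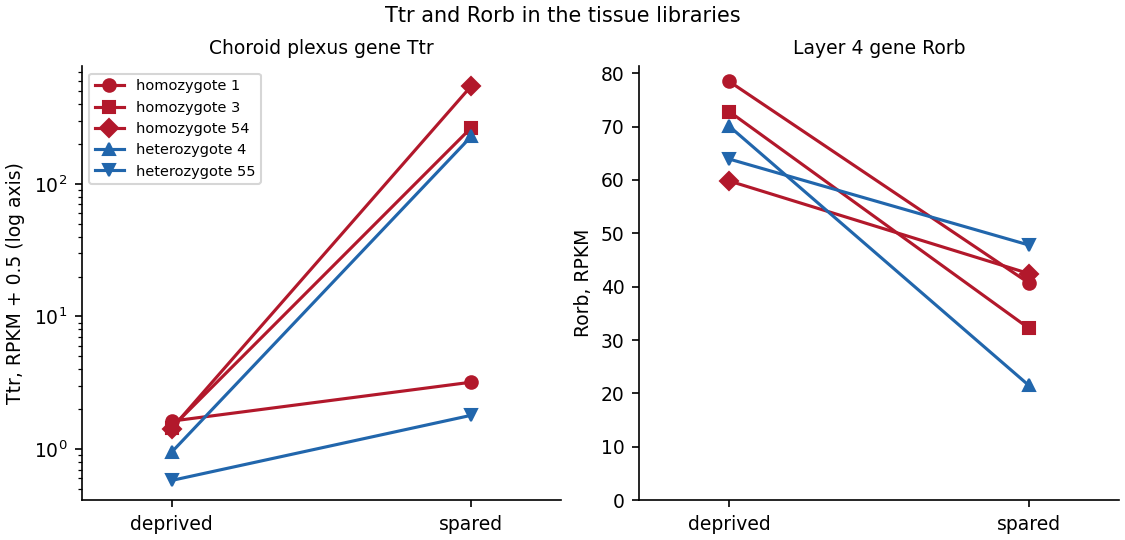
Ttr (RPKM + 0.5, log axis) and Rorb (RPKM) in deprived and spared tissue, with each line joining the hemispheres of 1 animal (homozygotes in red, heterozygotes in blue). Ttr reaches 547, 265 and 228 RPKM in the spared libraries of animals 54, 3 and 4, and Rorb is higher on the deprived side in 5 of 5 animals.

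Within homozygotes (3 against 3), Nrp2 was the gene that passed, with a log2 fold change of -2.48 ± 0.26 (SE, adjusted p 0.0325 by limma), while 945 genes had an unadjusted p under 0.05. The block gave 4 genes and edgeR 10, and leaving out 1 library gave 0 (without deprived 1, 3, 54, 4 or 55, or spared 3) to 20 (spared 55), with 11 without spared 1 and 19 without spared 4. By smallest p the next values were Zic5 (-1.42), Dusp4 (-1.06), Rerg (-1.42) and Palmd (-1.25) on the lower side and Trbj2-3 (2.13), Rasgrf2 (0.40), Fhod3 (0.64), Ptprk (0.77) and Ramp3 (0.75) on the higher side. Within heterozygotes (2 against 2) limma called 0 genes, with 457 at an unadjusted p under 0.05 and 1 by edgeR. There Nrp2 was at -2.66 ± 0.32, Dusp4 at -1.34, Epha6 at -1.30, Palmd at -1.38 and Zic5 at -1.48, and Cdh6 at 0.73, Cadm3 at 0.43, Trbj2-3 at 2.02, Cux2 at 1.02 and Hspb3 at 1.33. Without a filter on low RPKM 9 genes passed in heterozygotes, and leaving out spared 1, spared 4 or spared 55 gave 2, 1 and 1.

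The lesion response did not differ detectably between genotypes. The interaction gave 0 genes by limma and 0 by edgeR, with 107 at an unadjusted p under 0.05 by limma, and 3 genes without the filter. The values with the smallest p were SCARNA1 (2.48), Mir103-2 (2.60), U7 (1.54), Plp2 (0.62) and Nagpa (0.70) upward and Foxo1 (-0.86), Cxcl14 (-1.19), Snord104 (-2.38), Rgs2 (-1.26) and Mgp (-1.40) downward, each with an adjusted p of 1 by limma. Between homozygotes and heterozygotes (3 against 2 animals, hemispheres averaged) limma called 0 genes and edgeR 0, with 78 at an unadjusted p under 0.05 by limma, and without animal 1, 54 or 55 it called 2, 4 and 1. By smallest p these were Timm8a1 (0.81), Snord100 (1.09), Zfp874a (0.59), Atf1 (0.41) and U7 (0.90) higher, and Mgp (-1.10), Ctxn3 (-0.64), mt-Tp (-0.36), Tram1l1 (-0.35) and the complement gene C1qb (-0.63 ± 0.21 SE) lower in homozygotes.

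Of the microglial lists, the activated, marker and complement lists passed downward in homozygous tissue at the preset correlation, while the homeostatic list did not (5 measured, median log2 -0.01, adjusted p 0.893 by limma's camera). Of 32 lists, 13 passed camera with the preset correlation between homozygotes and heterozygotes, 11 down and 2 up, and none passed with an estimated correlation, where the lowest adjusted p was 0.570. All 13 measured genes of activated microglia were negative (median log2 -0.21, adjusted p 2.92e-07; adjusted p = 0.570 with an estimated correlation), led by Spp1 (-0.64), Cd68 (-0.38), Apoe (-0.37) and Lpl (-0.23). All 4 microglial markers were negative (median -0.50, adjusted p 5.26e-06; adjusted p = 0.570 with an estimated correlation), with Tyrobp at -0.50 and Ctss at -0.49, and complement genes passed downward (adjusted p 0.000221; adjusted p = 0.570 with an estimated correlation). Astrocyte (adjusted p 3.12e-05), cholesterol (8.43e-05), leptomeningeal (0.000254), interferon (0.00210), other ADAM and MMP (0.0147), fractalkine (0.0249), astrocyte reactivity (0.0353) and axon growth lists (0.0353) passed downward, and deep layer (0.0249) and thalamus or striatum lists (0.0249) upward, each at adjusted p = 0.570 or above with an estimated correlation. No member of any of the 13 lists passed adjusted over the list alone. Leaving out 1 animal gave 9 to 15 lists. Genotype is confounded with sex in this comparison: homozygotes 1 and 3 had Ddx3y at 13.5 to 19.1 RPKM and Xist at most at 0.00208 RPKM, while homozygote 54 and both heterozygotes had Xist at 0.899 to 1.52 RPKM.

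The fractalkine axis moved little in tissue. Adam10 (chromosome 9, 70678997 to 70780229, plus strand, GRCm38) was at 8.93 ± 0.994 RPKM in deprived and 7.81 ± 1.14 RPKM in spared tissue, higher in 5 of 5 animals, for which an exact sign-flip test of the 5 pairs gave p 0.0625, the smallest it allows. Its log2 fold change was 0.19 ± 0.11 (SE, adjusted p 0.490 by limma). Cx3cl1 (chromosome 8, 94772009 to 94782427, plus strand) was at 10.5 ± 3.08 against 12.2 ± 4.61 RPKM, higher in 1 of 5 animals (exact p 0.188). Adam17 (chromosome 12, 21323509 to 21373632, minus strand) was at 1.09 ± 0.121 against 1.13 ± 0.338 RPKM (1 of 5, exact p 0.812), and Ctss, cathepsin S (chromosome 3, 95526786 to 95556403, plus strand), at 1.04 ± 0.596 against 1.33 ± 0.276 RPKM (2 of 5, exact p 0.312). Over the 5 genes of the list the adjusted p values of these exact tests were 0.312 to 0.812.

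In single cells the ligand and the receptor lay in different cell types. Cx3cl1 was highest in the unnamed cluster 14, at 338 CPM, and next in neuron-like clusters, at 298 CPM in the Sst and Lhx6 inhibitory cluster (cluster 7) and 259 CPM in the Tle4 and Foxp2 excitatory cluster (cluster 3). It was at 22.2 and 30.1 CPM in both astrocyte-like clusters and 23.1 CPM in microglia-like cells. Cx3cr1 was at 785 CPM in microglia-like cells (cluster 16), of which 54.0% held a count at a median of 1624 counts per cell. This pools 1151 CPM and 76.6% of cells in heterozygotes with 68.4 CPM and 10.3% in knockouts. It was at 340 CPM in border macrophage-like cells (cluster 26; 483 CPM in heterozygotes and 72.2 CPM in knockouts) and at 3.72 CPM over all other clusters together, where 1.1% of cells held a count at a median of 2519 counts per cell. Adam10 was highest in endothelial-like cells (601 CPM) and next in microglia-like cells (327 CPM), and lay between 98.7 and 165 CPM in excitatory and inhibitory neuron-like clusters. Adam17 was highest in microglia-like cells (165 CPM), against 85.9 CPM in astrocyte-like cluster 4 and 8.61 CPM in the Rorb and Cux2 cluster. Ctss was at 1826 CPM in microglia-like cells, 883 CPM in border macrophage-like cells and 1.25 CPM over all other clusters. These levels pool cells of every library and were not tested between cell types.

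**Figure D3:**
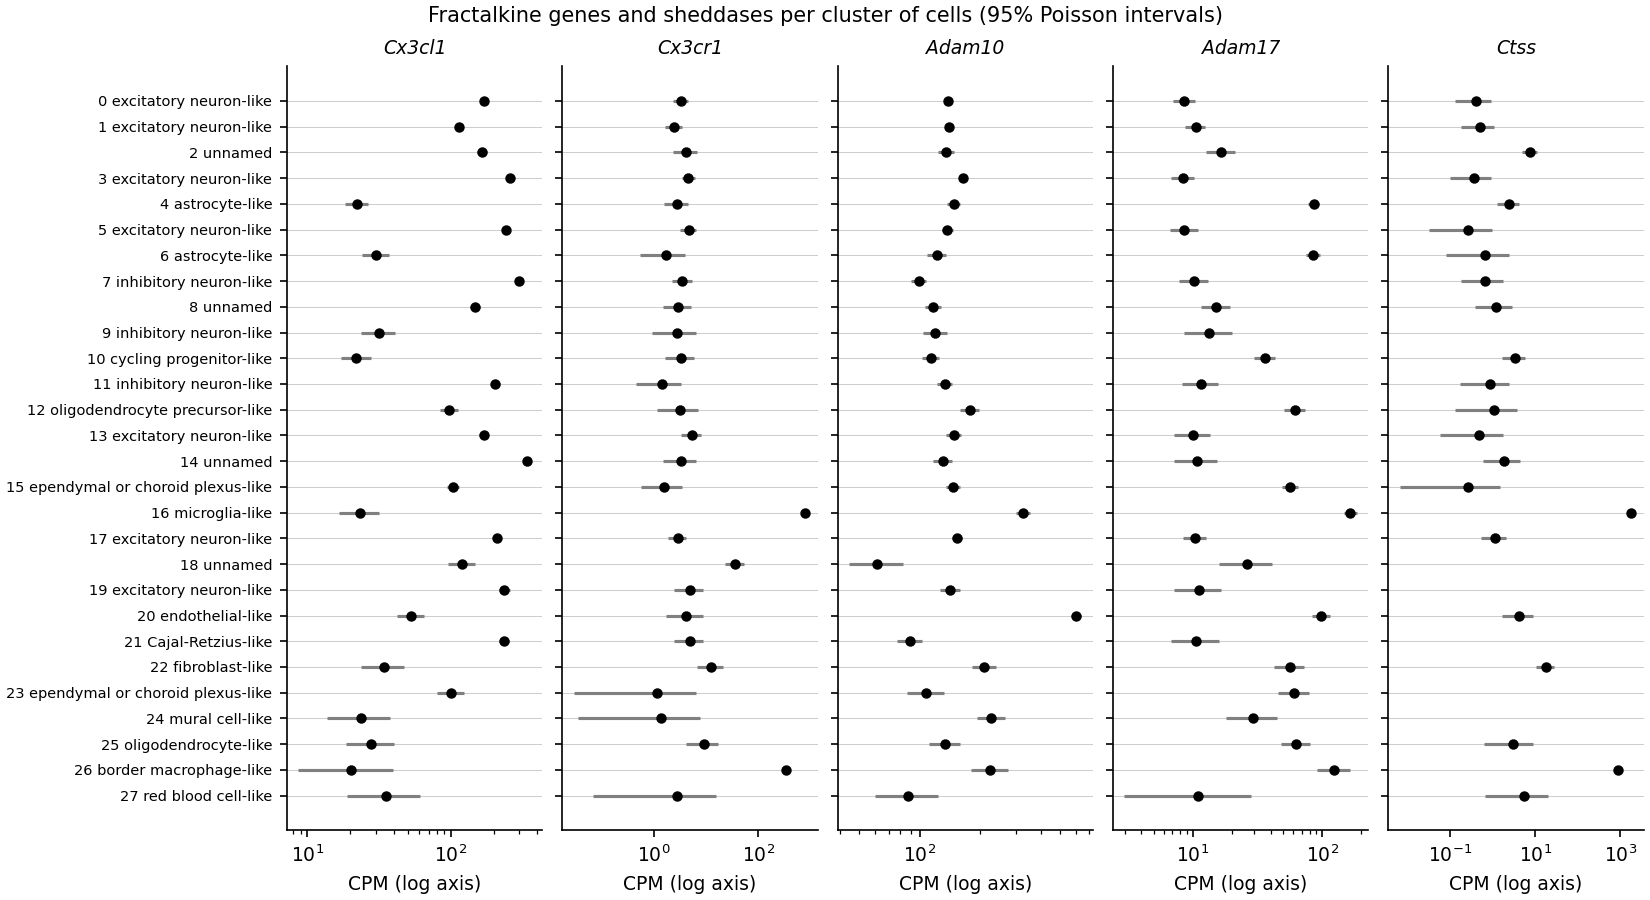
CPM (log axis) of Cx3cl1, Cx3cr1, Adam10, Adam17 and Ctss in the 28 annotated clusters, with bars for exact Poisson 95% intervals that cover counting error, and clusters with 0 counts not drawn. With genotypes pooled, Cx3cr1 stands at 785 CPM in microglia-like and 340 CPM in border macrophage-like cells, and Cx3cl1 at 338 CPM in cluster 14.

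Adam10 was higher in microglia-like cells of deprived hemispheres. With each library as 1 value it was at 394 ± 119 CPM in deprived and 256 ± 87.1 CPM in spared hemispheres (SD, n = 8), higher in 8 of 8 animals, with a mean difference of 139 ± 94.3 CPM. An exact two-sided sign-flip test gave p 0.00781, the smallest that 8 pairs allow, and 0.0391 after Benjamini-Hochberg adjustment over the 5 genes of the list. In heterozygotes the means were 375 ± 134 and 212 ± 38.6 CPM, and in knockouts 413 ± 120 and 300 ± 105 CPM (n = 4 each). It did not pass among all genes: edgeR on the sums gave a log2 fold change of 0.63 ± 0.23 (SE, adjusted p 0.999). With each library as a replicate edgeR gave 0.66 ± 0.17 (adjusted p 0.999). In the same fit Adam10 had log2 fold changes of 0.49 ± 0.33 in Cajal-Retzius-like cluster 21, 0.31 ± 0.21 in cluster 14 and 0.17 ± 0.09 in the Rorb and Cux2 cluster (cluster 0), each higher in 6 of 8 animals, and a median of 0.114 over the 19 other clusters. The other members did not pass by exact sign flips: Adam17 was at 180 ± 50.1 against 143 ± 35.6 CPM (6 of 8, exact p 0.141), Ctss at 1883 against 1823 CPM (5 of 8, exact p 0.680), Cx3cl1 at 25.7 against 21.2 CPM (3 of 8, exact p 0.844) and Cx3cr1 at 578 against 660 CPM (1 of 8, exact p 0.258). Within heterozygotes Cx3cr1 was at 1131 against 1219 CPM. Within knockouts the residual signal was at 24.8 ± 17.8 against 102 ± 32.3 CPM (n = 4) without overlap of the library values, which did not pass by edgeR on the sums. The deprived libraries held 0 to 3 counts, no more than a count of 0 allows, and the spared libraries 5 to 13. The use of single libraries as animals was chosen after their sex-linked transcripts had been seen, and the exact sign flips were added after the data were seen.

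**Figure D4:**
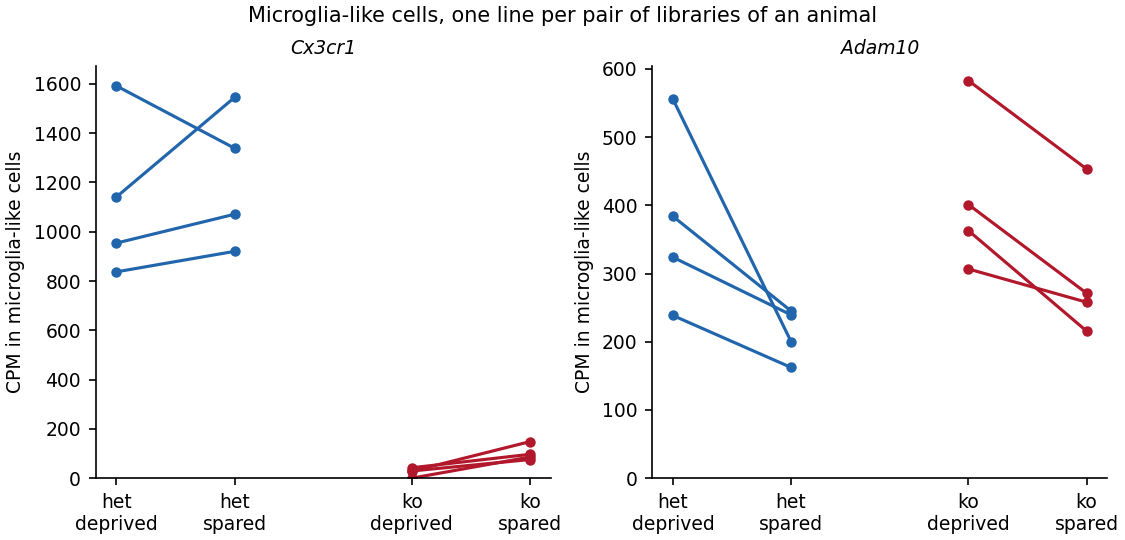
CPM of Cx3cr1 and Adam10 in microglia-like cells, with each line joining the deprived and the spared library of 1 animal (heterozygotes in blue, knockouts in red). Adam10 is higher on the deprived side in 8 of 8 animals, with means of 394 and 256 CPM.

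Across the whole transcriptome of microglia-like cells no gene passed between hemispheres. edgeR's quasi-likelihood test on the sums called 0 genes in heterozygotes, in knockouts, in both together and in the interaction, with 65, 150, 75 and 111 at an unadjusted p under 0.05, and DESeq2 called 0 in each. With the number of the sum as a block the counts were 0 in heterozygotes, 1 in knockouts, 1 in both together and 0 in the interaction. In heterozygotes the smallest p belonged to Ptn (log2 1.16 ± 0.40 SE), Xrn2 (1.08), Ddx10 (1.48), Htt (1.38) and Clasp1 (2.35) upward and to Nr4a2 (-4.19 ± 1.16 SE), Sox11 (-1.36), Tvp23b (-1.78), Klhl7 (-1.10) and Ndufs5 (-0.94) downward. In knockouts they belonged to Fnip1 (1.74), Tvp23b (1.96), Rab21 (1.47), Gda (2.18) and Man2a1 (1.45) upward and to Fxr1 (-2.03), Hsd17b10 (-2.36), the residual Cx3cr1 signal (-1.85), Fam65b (-2.56) and Zfand6 (-1.65) downward. In both together they were Ankrd11 (1.03), Gabpb2 (1.45), Sephs1 (1.24), Phc3 (1.09) and Lin9 (1.43) upward and Emd (-0.98), Ndufa12 (-1.11), Med11 (-1.29), Pik3cg (-0.85) and Hspbp1 (-0.85) downward. The interaction was led by Tvp23b (3.74), Gda (2.94), Aebp2 (2.08), Actr1b (1.69) and the histocompatibility gene H2-K1 (1.26) on the side of knockouts and by Fam65b (-3.83), Ptn (-2.15), Fxr1 (-2.23), Srpk2 (-2.29) and Acsl3 (-3.95) on the other.

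Among gene lists, 3 passed in microglia-like cells of heterozygotes by camera with the preset correlation, and none with an estimated correlation. Immediate early genes passed downward (9 tested, median log2 -0.73, adjusted p 0.0222; adjusted p = 0.685 with an estimated correlation; 1 lower adjusted over the list alone), as did deep layer neuron genes (4 tested, median -0.91, adjusted p 0.0222; adjusted p = 0.548 with an estimated correlation; 1 lower adjusted over the list alone). Nr4a2 is in both lists, with Egr1 (-2.51), Fos (-1.36) and Junb (-0.88) in the first and Tbr1 (-1.06), Bcl11b (-0.75) and Tle4 (0.11) in the second. Presynaptic genes passed upward (9 tested, median 0.35, adjusted p 0.0222; adjusted p = 0.548 with an estimated correlation; 0 adjusted over the list alone), with Syt4 at 0.85, Sv2a at 0.73, Cplx2 at 0.63 and Stx1a at 0.60. Tbr1, Bcl11b, Syt4 and Cplx2 are transcripts of neurons. Nr4a2 is among the leading genes of excitatory cluster 5 and of the unnamed cluster 2. Whether RNA of neurons accounts for these 3 lists was not tested. Homeostatic, activated and complement genes did not pass, each at an adjusted p of 0.922 (edgeR with camera).

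In the other clusters few genes passed between hemispheres, and those that did are transcripts of other cell types. Over 21 clusters with at least 20 cells in each sum, edgeR called 0 genes in heterozygotes (1779 at an unadjusted p under 0.05; 4 by DESeq2), 1 in knockouts (2404; 10 by DESeq2) and 1 in both together (2331; 6 by DESeq2). Sst, the somatostatin of inhibitory neurons, was lower in deprived oligodendrocyte precursor-like cells (log2 -3.63 ± 0.53 SE, adjusted p 0.00249 by edgeR), and Nrgn, neurogranin of excitatory neurons, was higher in deprived mural cell-like cells of knockouts (3.38 ± 0.59 SE, adjusted p 0.0228 by edgeR). With the number of the sum, which stands for 2 animals, as a block the counts were 74 in heterozygotes, 31 in knockouts and 26 in both together, and with each library as a replicate and the animal as a block they were 31, 19 and 17. Leaving out 1 sum moved the count in heterozygotes to 37 (without heterozygous spared 2), 28 (heterozygous spared 1), 8 (heterozygous deprived 2), 5 (knockout spared 1), 3 (heterozygous deprived 1 or knockout spared 2) and 1 (knockout deprived 1). In knockouts the sums of heterozygotes gave 10, 11, 13 and 10 when left out (deprived 1 and 2, spared 1 and 2), and knockout spared 1 and 2 gave 9 and 4. In both together the count was 16 without heterozygous spared 2, 9 without heterozygous deprived 2, 4 without heterozygous spared 1, 3 without knockout spared 2 and 0 without knockout deprived 2. The interaction called 1 gene (2025 at an unadjusted p under 0.05; 2 by DESeq2; 48 with the block), again Nrgn in mural cell-like cells (4.99 ± 0.81 SE, adjusted p 0.00732 by edgeR), from sums of 6 to 88 counts. Without 1 sum the interaction called 27 (heterozygous spared 1), 8 and 3 (heterozygous deprived 2 and 1), 6 (heterozygous spared 2), 5 (knockout deprived 1 or spared 1), 4 (knockout spared 2) and 0 (knockout deprived 2).

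Between knockouts and heterozygotes, Cx3cr1 was the one gene called in microglia-like cells (log2 -4.15 ± 0.33 SE, adjusted p 2.87e-06 by edgeR; 136 at an unadjusted p under 0.05; 1 by DESeq2). The other values with the smallest p were Folr2, a folate receptor of macrophages (-2.17), Ramp1 (-1.91), Ctdsp1 (-2.44) and Wdr81 (-2.44) lower in knockouts, and the metallothionein Mt2 (1.40), Ppp2cb (1.74), Ttr (2.87), Atrn (1.23) and Lgalsl (1.94) higher, each at an adjusted p of 0.999 by edgeR. Over all clusters edgeR called 4 genes (2448 at an unadjusted p under 0.05; 4 by DESeq2): besides Cx3cr1 these were the haemoglobin gene Hbb-bs in oligodendrocyte precursor-like cells (-2.93), Xist, the transcript of the inactive X chromosome, in Cajal-Retzius-like cells (-2.58), and the collagen gene Col8a1 in fibroblast-like cells (-8.00). Each sum mixes a male and a female library, so that a call in Xist follows the share of cells of each sex. Leaving out 1 sum moved the count over all clusters to 64 (heterozygous 1), 223 (heterozygous 2), 76 (knockout 1) and 123 (knockout 2), and that in microglia-like cells to 3, 7, 2 and 9.

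With each animal as a replicate (4 against 4, sex and sample number as covariates), a unit chosen after the sex-linked transcripts had been seen, edgeR called 7 genes between knockouts and heterozygotes in microglia-like cells and 211 over all clusters. In microglia-like cells these were Cx3cr1 (log2 -4.03 ± 0.20 SE), Spp1 (-1.69 ± 0.28), Apoe (-0.67 ± 0.12), Gpnmb (-1.37 ± 0.29), Itgax (-1.36 ± 0.30) and Folr2 (-2.26 ± 0.50), lower in knockouts, and Ttr (2.06 ± 0.37). The Ttr call rests on 1 knockout animal at 2120 CPM, the others being at 0, 104 and 146 CPM against 0 to 226 CPM in heterozygotes (exact permutation p 0.629). Apart from Cx3cr1, the called genes without overlap between animals were Apoe and Folr2 (exact permutation p 0.0286 each, the smallest that 70 arrangements allow), and other groupings of the 8 animals gave as many calls.

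**Figure D5:**
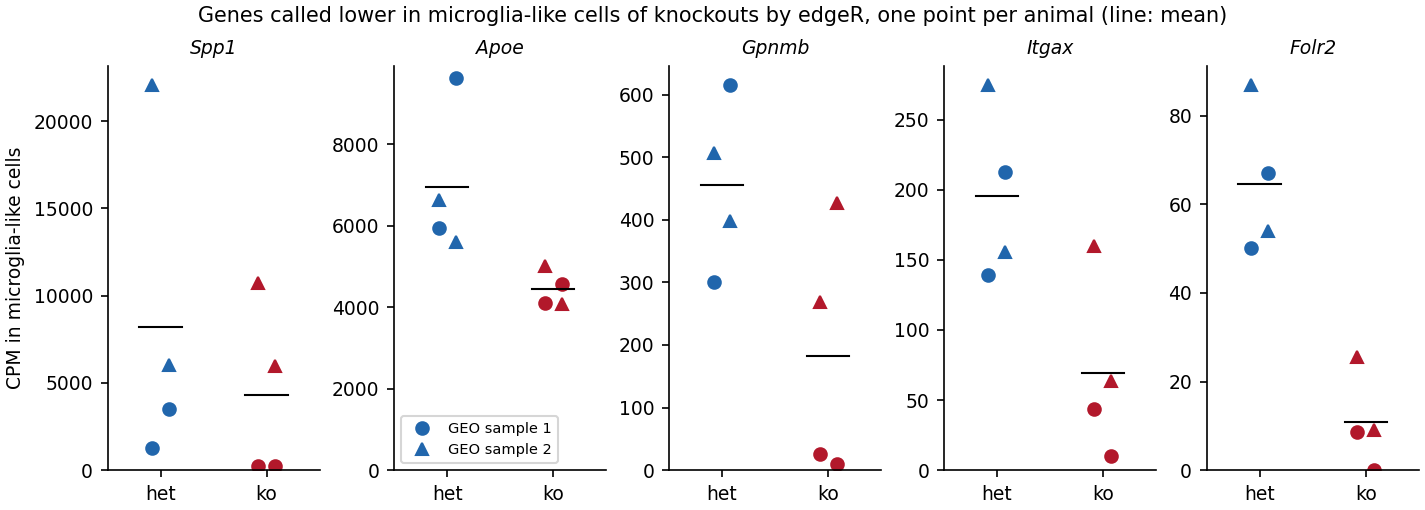
CPM of 5 genes in microglia-like cells of heterozygotes (blue) and knockouts (red), with 1 point per animal, circles for GEO sample 1, triangles for GEO sample 2 and lines for the means. Apoe and Folr2 do not overlap between genotypes, with means of 6952 and 4440 CPM for Apoe, while Spp1, Gpnmb and Itgax do.

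The cell-type makeup did not differ detectably between hemispheres. Microglia-like cells were 2.56 ± 1.33% of annotated cells in deprived and 2.37 ± 0.660% in spared sums (SD, n = 4; exact permutation p 0.800). The smallest p belonged to endothelial-like cells, 1.93 ± 0.534% against 1.36 ± 0.281% (exact permutation p 0.0857, adjusted p 0.985), and 0 of 28 clusters passed. With 4 against 4 sums the exact test cannot go below p 0.0286, so that a single changed cluster cannot pass the adjustment over 28 clusters. Over pairs of libraries, clusters 19 and 24 had the lowest p, 0.0156 and 0.0234 (exact sign flips, adjusted p 0.328 each). Both had the larger share on the deprived side in 7 of 8 animals, as had clusters 20 and 23.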

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

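The tests named here were fixed in kind before the values were seen, and no explanation was tested for these values, technical or biological. A sample counted as far from the others when its gap to the nearest one was a large part of the range of its group by Dixon's criterion. Chance puts about 1 in 20 groups past that limit: of 126 groups tested, 11 passed and 6.3 would by chance.

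In deprived tissue Hspb3 was lowest at 10.01 RPKM, with the next library at 11.2 RPKM, and Nrn1 was highest at 6.13 RPKM, with the next at 4.99 RPKM. Both lie on the same side of their spared libraries as the other animals do.

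The other values far from their group were shares of cells in single sums. Among deprived sums, the highest share was 6.91% in astrocyte-like cluster 6 (next 4.91%), 5.38% in inhibitory cluster 7 (next 4.04%), 8.21% in inhibitory cluster 9 (next 3.78%), 6.30% in excitatory cluster 17 (next 0.549%) and 2.96% in mural cell-like cluster 24 (next 0.920%). Among spared sums, excitatory cluster 19 was lowest at 0.345% (next 1.73%), and the highest share was 1.77% in mural cell-like cluster 24 (next 0.723%), 0.885% in border macrophage-like cluster 26 (next 0.494%) and 1% in red blood cell-like cluster 27 (next 0.324%).

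The difference between hemispheres in Nrgn counts of mural cell-like cells differed between knockouts and heterozygotes by a log2 of 4.99 (adjusted p 0.00732 by edgeR's interaction test). Nrgn is a transcript of excitatory neurons, and these sums held 6 to 88 of its counts. The sums of deprived knockouts held 1067 and 1736 CPM against 206 and 82.3 CPM in spared knockouts, and heterozygotes held 157 and 56.6 CPM deprived against 184 and 525 CPM spared.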

How the results depend on the processing

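The alternatives added after the results were seen are edgeR on tissue, the fit without animals 3, 4 and 54, the covariate (a score of 52 leading genes of clusters 8, 13 and 17), each library as a replicate, and the gene list tests with the block and an estimated correlation or without single libraries. Over 19 counts of calls there were 306 alternative values, of which 176 lay within 1.5 times the reported count, 40 below and 90 above. Where a count moved the cause was not tested unless named.

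In tissue, the 72 genes between hemispheres became 14 without a filter, 31 with a mean of at least 5 RPKM, 364 with the animal as a block (72 shared), 280 with edgeR (71 shared), 950 with edgeR and the block, 0 without animals 3, 4 and 54 (which leaves 2 animals, too few to speak of stability) and 0 with the block and the covariate, and 14 (spared 3) to 524 (spared 55) without 1 library. The named genes kept their direction wherever they were measured (20 genes in most alternatives, 19 with edgeR, 9 with a mean of at least 5 RPKM). Of the 20, 0 stayed past the threshold with the covariate, 0 without animals 3, 4 and 54, 1 without a filter and 5 to 20 without 1 library. With the covariate the median log2 fold change of the lower genes went from -1.09 (median SE 0.128, block) to -0.91 (median SE 0.261), and 58 of 59 kept their sign, so that the wider SE contributed to the loss of calls. The score was higher on the spared side in 5 of 5 animals and its genes were chosen after the values were seen, so that this fit says little on stability. In homozygotes the count of 1 became 0 with pseudocount 1, 0 with a mean of at least 5 RPKM, 2 without a filter, 4 with the block, 10 with edgeR and 0 to 20 without 1 library. In heterozygotes 0 became 9 without a filter, 1 with median scaling, 1 with edgeR and 0 to 2 without 1 library. The interaction gave 3 without a filter. Between genotypes, leaving out 1 animal gave 0 to 4.

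Of the tissue gene lists, the 11 between hemispheres became 0 with an estimated correlation, 0 with the block and an estimated correlation and 7 to 14 without 1 library. The 13 between genotypes became 0 with an estimated correlation. The 3 lists in microglia-like cells became 0 with an estimated correlation, 1 with each library as a replicate and the block, and 0 with that fit and an estimated correlation. The list that still passed was immediate early genes.

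In cells, counts over all clusters are given for heterozygotes, knockouts, the interaction and both genotypes together (reported 0, 1, 1 and 1). They were 4, 10, 2 and 6 with DESeq2; 120, 83, 47 and 169 with at least 1 count in total; 7, 10, 9 and 12 with a mean of at least 10 CPM; 74, 31, 48 and 26 with the number of the sum as a block; 31, 19, 22 and 17 with each library as a replicate and the block; 3, 0, 2 and 0 with each library as a replicate and no block. With cells of at least 1000 UMIs the knockouts and the interaction gave 0. Library 1 of each hemisphere alone gave 2, 8, 1 and 0, and library 2 alone gave 6, 0, 0 and 3. Adjusted over all cell types together, each of the 4 gave 0. Without 1 sum they ranged over 0 to 37, 1 to 13, 0 to 27 and 0 to 16.

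In microglia-like cells the counts of 0 became 3, 1, 1 and 4 with at least 1 count in total, and 1 in knockouts and 1 in both together with the block; without 1 sum heterozygotes gave 0 to 2. Between genotypes the count of 4 over all clusters became 106 with at least 1 count in total, 25 and 1 with library 1 or 2 alone, 211 with each animal as a replicate, 2 adjusted over all cell types and 64 to 223 without 1 sum; in microglia-like cells 1 became 6 with at least 1 count in total, 7 with each animal as a replicate and 2 to 9 without 1 sum. The block changed no other call. Leaving out 1 of 2 sums leaves a lone sum, assumed to vary like the other groups. Shares of cell types gave 0 in 12 alternatives, which shows no stability, since a single changed cluster cannot pass at these sizes.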

Other observations

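The tests in this part were chosen after the results were seen, apart from edgeR on the sums, which was planned. With each animal as a replicate, and sex and sample number as covariates, 4 of the 20 tested genes of the activated microglia list were called lower in knockout microglia-like cells and 16 did not pass; 17 of the 20 were negative. Besides Cx3cr1, edgeR called Spp1 (log2 -1.69 ± 0.28 SE, adjusted p 0.000567), Apoe (-0.67 ± 0.12), Gpnmb (-1.37 ± 0.29), Itgax (-1.36 ± 0.30) and the folate receptor gene Folr2 (-2.26 ± 0.50) lower, and Ttr (2.06 ± 0.37), whose direction rests on 1 knockout animal at 2120 CPM (exact permutation p 0.629). Apoe was at 6952 ± 1839 CPM in heterozygotes and 4440 ± 437 CPM in knockouts (SD, n = 4), and Folr2 at 64.5 ± 16.5 and 10.8 ± 10.6 CPM, each without overlap (exact permutation p 0.0286, the smallest that 70 arrangements allow). Gpnmb was at 455 against 183 CPM and Itgax at 196 against 69.3 CPM (exact permutation p 0.0857 each). Spp1 differed more between the samples than between genotypes, at 2402 against 228 CPM in sample 1 and 14030 against 8343 CPM in sample 2 (exact permutation p 0.571). On the sums, the adjusted p of all but Cx3cr1 was 0.999 by edgeR. P2ry12 (0.04), C1qa (-0.11), Tmem119 (0.61), Mrc1 (-0.68, without overlap between animals, exact permutation p 0.0286) and the activation genes Cd68 (-0.64), Igf1 (-0.63), Lpl (-0.28) and Clec7a (-0.34) did not pass.

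Chance was not excluded for these counts. Of 33 splits of the 8 animals, 3 gave at least the 7 genes of microglia-like cells, the real split included, with 16 as the highest other, and 2 gave at least the 211 genes over all clusters, the real split included, with 376 as the highest other. A lower level of some activation genes without Cx3cr1 may be a real effect, but these 3 of 33 splits leave chance open.

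For the tissue count, 2 of 100 splits of the 10 libraries that ignore the pairs gave at least 72 genes, the real split included, with 108 as the highest other, a share under 0.05. Of the 16 splits that part every pair, the real one gave 72 and the highest other 0, or 364 and 0 with the block, but 16 are too few for a share under 0.05. Within homozygotes the 10 splits are too few for a share under 0.05 (real 1, highest other 0). For the gene lists between hemispheres 11 of 100 splits gave at least 11 lists, with 14 as the highest other, so that chance was not excluded. For cells in both genotypes 17 of 22 splits gave at least 1 gene, with 36 as the highest other, so that chance was not excluded. With the number of the sum as a block, 7 of the 8 splits that part every pair gave at least the real 26 genes, with 99 as the highest other. In microglia-like cells 5 of these 8 gave at least the real 1, with 4 as the highest other. In microglia-like cells the real count is 0, which all 22 splits reach by construction (highest other 1), so that the splits say nothing there. The split that follows the GEO sample number gave 22035 genes, which points to a structure of the libraries whose cause was not tested.

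The source of the genes lower in deprived tissue, and of those higher, stays open. Of the lower genes with a level in the cells, 10% (5 of 50) were highest in clusters 15 or 23, which the fixed marker lists name ependymal or choroid plexus-like, against 11.7% of the genes not changed (Fisher's exact p 1, against all other tested genes). No excess was seen among these genes, which neither supports nor excludes choroid plexus tissue in the spared libraries as a source. The leading genes of cluster 15 had a median tissue log2 fold change of -0.736. Their median was negative in 5 of 5 animals, though at -0.025 in animal 55. They did not pass with an estimated correlation (adjusted p 0.316 by limma's camera). Ttr was at 228 to 547 RPKM in 3 of the 5 spared libraries, while the lower genes had the same sign in 5 of 5 animals, also in animals 1 and 55 with 2.69 and 1.3 RPKM. In the spared libraries of animals 1 and 55 Ttr was still above its level in all 5 deprived libraries. This sign therefore does not separate choroid plexus from other sources. The marker lists place no cluster in another brain region, and clusters picked for this after the values were seen would decide nothing. In the excitatory clusters 0, 1, 3 and 5, 25 of the 59 lower genes could be tested, as 71 values of gene and cluster. Genes tested in several clusters count more than once, and excitatory neuron-like clusters 13, 17 and 19 were not part of this check. Over these 71 values the median log2 fold change was 0.0471 (quartiles -0.18 and 0.18), against -0.97 in tissue. That argues against lower expression within these neurons as the whole cause for these 25, and it stays open for the other 34. Of the higher genes, 10 could be tested there, as 29 values of gene and cluster. Their median log2 fold change was -0.0483 (quartiles -0.12 and 0.07), against 0.66 in tissue. That argues against higher expression within these neurons as the whole cause for these 10, and it stays open for the others. A left-right difference without lesion cannot be told apart from the lesion, because 0 animals had a right deprived hemisphere.

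Genes called between hemispheres with each library as a replicate may largely be free RNA of other cell types; doublets were not tested. Of 67 calls, 83.6% were of transcripts at less than 1 in 4 of their level in the highest cluster, against 19.6% of tested genes, which argues against transcripts that the cluster itself makes. Of these calls 78.6% had the sign of the other clusters with low levels in the same contrast. Cluster 2 held more of the 67 calls than any other cluster. It has no name and a median of 745 counts per cell, so that which cell types are other to it is not settled. The 3 contrasts share libraries and some calls, so that the calls are not independent and no p is given.

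Adam10 in microglia-like cells may respond to the lesion, but chance among many genes stays open: it was the 1 gene of 3643 with a p as small, where 2.15 are expected. With each library as a replicate its log2 fold change in microglia-like cells was 0.66. A library-wide shift of that size is argued against by the median of 0.114 over the other 19 clusters (0.49 ± 0.33 SE in cluster 21). Of these 19, 14 were positive, so that a smaller rise shared by cell types is not excluded. The deprived library held more microglial counts in 3 of 8 pairs, all of heterozygotes, and fewer in every pair of knockouts. That argues against a depth difference in 1 direction over both genotypes, while depth stays open within knockouts.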
